A study of Mus musculus with 33 samples.

How the data were processed

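The series holds single-cell RNA sequencing of the hippocampal neurogenic niche of C57BL/6 mice, the region around the dentate gyrus where neural stem cells give rise to new neurons. Per the labels, hippocampal tissue was depleted of neurons, live cells negative for the antibodies against GluR1 and Cd24 were sorted singly into 384-well plates with spike-in RNA, and libraries were made by SORT-seq, a plate-based form of CEL-Seq2 that reads the 3' ends of transcripts with a cell barcode and a unique molecular identifier (UMI). Sequencing was paired-end on a NextSeq500, per the labels. The labels give 31 niche libraries from 5 numbered experiments, 1 library from mice older than 12 months and 1 library of GFP-positive hippocampal cells of Nestin-GFP mice. The age of the niche and Nestin-GFP mice is not given in the sources used here, so "younger" for the niche experiments is an assumption. The experiment was the replicate, because libraries and cell classes of one experiment share a sort. Where classes were compared within experiments, p-values measure how far the difference between classes varied from one experiment to another. The tests with edgeR share the estimate of this spread between genes. With 2 experiments, as in the pairs with stem cell-like cells, p-values rest in large part on that shared estimate. For the old library p-values measure the spread between the niche experiments. Nothing in the labels says how many mice an experiment holds, so either may be technical.

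Reads were aligned with BWA 0.6.2-r126 to mm10, per the submitters' processing notes. The gene annotation and the counting tool are not given in the sources used here. The deposited values are estimated counts of transcripts per gene and well, which the authors had corrected for UMI saturation, so most are not whole numbers. Inverting the saturation formula gave whole UMI numbers within 0.05 for 99.33% to 100% of the values of a library, with a pool of 256 UMIs in most libraries and of 4096 in plates H, I and L and in the old and Nestin-GFP libraries, whereas the labels state a UMI of 4 bases. The estimated counts as deposited were rounded to whole numbers for the tests. A further deposited table holds 1536 cells and 12469 genes, with each value a whole number plus a constant of 0.1 and with 1407 to 1498 transcripts per cell. Its cells were 1109 niche, 128 old and 299 Nestin-GFP cells, all with at least 1500 transcripts in the count files, where 2 further wells reached that number. It served only to choose cells in an alternative. For the 5 libraries of 384 wells, the record of units lists the first wells only; the inversion above covered all wells. An author annotation of cell types was not used here.

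Wells with at least 1000 transcripts were kept as cells, without spike-ins and mitochondrial genes. Mitochondrial genes were left out because they are listed in the old and Nestin-GFP files alone. No doublet caller was run. Cells that held 3 or more markers of a second, unrelated class were left out in an alternative instead. The UMIs of each cell were divided at random into 2 sets. Cells were clustered on the first set (scale of 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1), clusters with astrocyte, stem cell or progenitor markers were clustered once more, and all tests used the second set. A cluster was named from 15 fixed marker sets, of which 158 genes are in the files, where the best marker score reached 0.5 with at least 3 markers in at least 10% of its cells. In the second round a stem cell, progenitor or neuroblast name came from the fold within these clusters, and any other name from the fold against all other cells by the same rule. All clusters of astrocyte-like cells were named in the latter way, as within the second round their scores were 0.05 to 0.41. Classes are called "-like" because their names rest on markers. Marker genes are given only as the identity of a class. No class was named from the ependymal, choroid plexus, mural or perivascular macrophage sets. Markers, gene lists, tests and most alternatives were fixed before the data were examined. The naming thresholds were set after that, and the class assignment was revised 2 times after gene-level results had been seen, first when mitochondrial genes were left out and then when a single random division of UMIs was used throughout. After these revisions the number of genes differing between stem cell-like and astrocyte-like cells was lower and the number differing between old and younger niche cells fell to near 0. Only results of the last assignment are given.

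Counts of the second set were summed per experiment and class and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) with experiment as a block. The pairing rests on the experiment numbers of the labels, since both classes of a pair come from the same sort. In the oligodendrocyte lineage pair, deviations from the class means correlated across 1816 genes by 0.366, 0.302 and 0.0631 in experiments 1, 3 and 5. A pair of classes was fitted over the experiments with at least 5 cells of both. Each of the 7 classes with 5 cells in at least 3 experiments was compared with the mean of the other 6. The old library was compared with the younger experiments, without a covariate, for classes with at least 10 old cells, so a single old library was assumed to vary like the younger experiments. Fixed gene lists, 25 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and calls of single genes were also adjusted over the list alone. The list of ribosomal proteins was drawn by symbol and also holds ribosomal S6 kinases such as Rps6ka1 and Rps6kb1. The list of mitochondrial genes gave no result.

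Shares of classes were not tested. Shares of a single library carry 95% exact Clopper-Pearson intervals, and a count of 0 is given with the share that 3 cells would make. All such intervals cover counting error only. Levels in CPM, counts scaled to one library size, are means over experiments with their SD. Single genes of the comparisons are given after TMM scaling as CPM of the counts of the tested genes alone. They therefore lie above CPM of the total counts, and levels from different comparisons cannot be set side by side. Ptprz1 in the oligodendrocyte pair, for one, stood at 3033 CPM of the total counts of precursor-like cells, summed over experiments. Summed levels of markers, lists and haemoglobin are given as CPM of the total counts. For a gene with 0 counts in one class of a pair the fold is a lower bound from 3 counts over the group, and with 1 to 3 counts a ratio of summed CPM is given with its 95% counting interval.

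The genes named for a pair were the 8 highest and 8 lowest fold changes among called genes with at least 50 CPM and one direction in every experiment, with the 2 smallest adjusted p of each list. For a class they were the 4 highest and up to 3 higher members of each list, and for the old library the 5 highest and 5 lowest and 2 of each list. Marker genes, predicted gene models and pseudogenes were left out. Some genes that this rule names are not reported here. Coordinates are those of GENCODE vM21, matched by symbol and chromosome for 17612 of 18888 genes (93.24%). Gene models that overlap or share sequence cannot be told apart in these counts where the counting is not stated.

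In all, 28 alternatives were run, among them other transcript minimums, resolutions, divisions of UMIs, raw UMIs, scalings, DESeq2 1.42.0, no gene filter, counts per plate, no block and each experiment left out. Mitochondrial genes counted toward the minimum, other random divisions, the stricter second-class filter, a minimum of 3 cells and the cells of the deposited table were chosen after the data were seen. Count tests were first tested on simulated counts with 200 changed genes. For a log2 change of -2, -1, 1 and 2, recovery was 61.3%, 19.4%, 14.6% and 88% for stem cell-like against astrocyte-like cells (1402 genes). It was 84.6%, 6.67%, 8.33% and 90% for the neurogenic pair (1805 genes), and 84.4%, 35.7%, 31.1% and 96% for the oligodendrocyte pair (1106 genes). For classes it was 97.2%, 42.1%, 77.5% and 100% (3042 genes). In the old comparison a rise of 2 was recovered in 6.52% of blood and lymphoid-like (1276 genes), 30.6% of microglia-like (2880 genes), 44.7% of neuroblast-like (6485 genes) and 66% of precursor-like changes (3351 genes), and a fall of 2 in 0%, 0%, 2.22% and 12.8%. Unchanged genes were called in at most 0.566% of cases, a rate per unchanged gene. Among all calls, the share of unchanged genes exceeded the adjusted p threshold in most comparisons. It did not in the oligodendrocyte pair and in old blood and lymphoid-like cells. In old neuroblast-like cells 10 unchanged genes were called, beside 21 with a rise of 2 and 1 with a fall of 2. In old microglia-like cells 3 unchanged genes were called, beside 15 with a rise of 2. Software was R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.

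Summed transcripts ranged from 29427 to 828822 per niche library. A library deposited more than once was looked for among the 528 pairs of the 33 libraries, and none was found, the lowest chi-square per degree of freedom being 1.56. Plates D and E of experiment 3 hold haemoglobin under other symbols than plates C and H. The old library has counts under both, and plates A, B, F, I and L have none. In plates D and E 170 symbols above 30 CPM elsewhere are at 0, so genes of experiment 3 rest mostly on plate F with 106 of its 155 cells. Experiment 2 was resequenced, and per the file names its plates share a run, as do the old and Nestin-GFP libraries.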

Results

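The transcriptomes of single cells were measured in the hippocampal neurogenic niche of the mouse, after neurons had been depleted and live cells negative for GluR1 and Cd24 had been sorted. GluR1 is a glutamate receptor subunit of neurons and Cd24 is carried by neuroblasts among other cells. The question, as the series states it, was which cell types make up the niche when it is sorted without selection for a single type. From 3840 wells in 31 niche libraries, 1285 wells (33.5%) held at least 1000 transcripts. The 5 experiments gave 435, 381, 155, 141 and 173 cells, with a median of 3526, 6121, 4055, 12392 and 1943 transcripts per cell and 1788676, 2658266, 989464, 1855527 and 568538 transcripts in all. The library of mice older than 12 months gave 138 cells of 384 wells (35.9%), with a median of 4394 transcripts per cell and 782031 in all. The Nestin-GFP library, of GFP-positive hippocampal cells per the labels and named for a fluorescent reporter under the promoter of the neural progenitor gene Nes, gave 315 cells of 384 wells (82%), with a median of 5948 transcripts per cell and 1982172 in all.

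The niche sort held glia, immune cells, vessel cells and cells of the neurogenic lineage. Microglia-like cells made up 21.8% ± 11.4 (SD, n = 5 experiments) of cells, neuroblast and immature neuron-like cells 18.9% ± 18.8, astrocyte-like cells 18.8% ± 7.46 and oligodendrocyte precursor-like cells 17.2% ± 10.4. Blood and lymphoid-like cells followed with 7.53% ± 3.46, mature oligodendrocyte-like cells with 4.39% ± 4.74, neural stem cell-like cells with 3.35% ± 3.55 and proliferating progenitor-like cells with 2.86% ± 3.58. Fibroblast-like cells (2.35% ± 3.87), endothelial-like cells (2.10% ± 1.76) and mature neuron-like cells (0.763% ± 0.783) were the least frequent. Stem cell-like, proliferating and neuroblast-like cells together made up 25.1% ± 21.9, from 3.91% to 57.4% in single experiments. The neuroblast-like share ran from 1.84% to 48.2%, so its SD was as large as its mean, and these cells were recovered although the gate removes Cd24-positive cells.

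The identity of each class rests on its fixed markers. Astrocyte-like cells carried 30554 ± 4626 CPM of astrocyte markers (SD, n = 5 experiments), and stem cell-like cells 18863 ± 7376 CPM of these beside 6768 ± 730 CPM of stem cell markers (n = 2), against 3046 ± 877 CPM of stem cell markers in astrocyte-like cells. Microglia-like cells carried 43521 ± 5750 CPM of microglia markers and mature oligodendrocyte-like cells 93818 ± 9639 CPM of oligodendrocyte markers. Neuroblast-like cells carried 10030 ± 1287 CPM of their own markers and 1964 ± 378 CPM of proliferating progenitor markers. Their cluster 6, led by Eomes of the progenitor set, held 7, 44, 13, 34 and 2 cells in experiments 1 to 5. Cluster 4, led by Prdm8 and Neurod1, held 1, 51, 11, 12 and 5, so the class is not shown to be a single stage. The blood and lymphoid-like class was mixed. It carried 83696 ± 182760 CPM of its own markers, 11043 ± 16375 CPM of choroid plexus markers and 2224 ± 2723 CPM of microglia markers. Its cluster 11, led by Ccl5, Gzma and Nkg7, genes of cytotoxic lymphocytes, held 13, 17, 1, 13 and 7 cells in experiments 1 to 5, and its cluster 12 held 1, 30, 10, 0 and 3. Fibroblast-like cells carried 22901 ± 20127 CPM of mural cell markers beside 13572 ± 13874 CPM of fibroblast markers (n = 2).

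**Figure D1:**
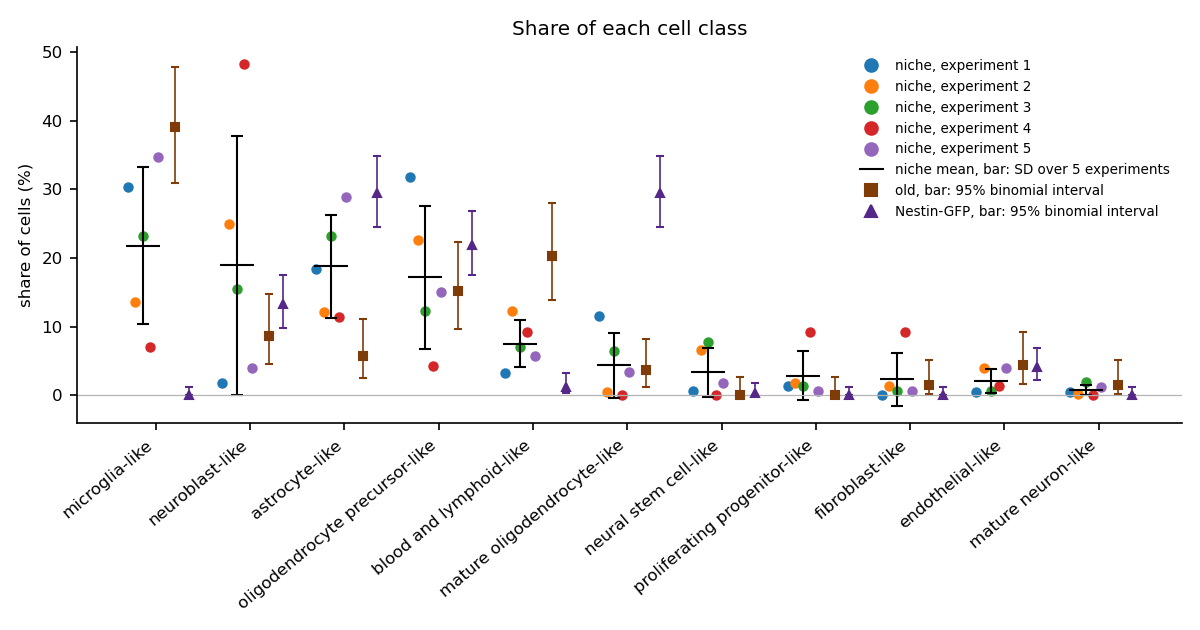
Share of cells (%) of each class in the 5 niche experiments (dots), with their mean (black line) and SD (bar), beside the old library (brown square) and the Nestin-GFP library (purple triangle) with 95% binomial intervals. Microglia-like cells made up 39.1% of the old library and 0 of 315 cells of the Nestin-GFP library, against a niche mean of 21.8%.

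In the library of older mice, microglia-like and blood and lymphoid-like cells each took a larger part of the sort than in any younger experiment. Microglia-like cells made up 39.1% of its cells (95% interval 30.9 to 47.8), above all 5 younger experiments (7.09% to 34.7%), though the interval includes the highest of these. Blood and lymphoid-like cells made up 20.3% (13.9 to 28), also above all 5 (3.22% to 12.3%). Endothelial-like cells (6 cells, 4.35%, 1.61 to 9.22) lay just above the highest of the 5 (0.46% to 4.05%). Astrocyte-like cells made up 5.80% (2.54 to 11.1), below all 5 (11.3% to 28.9%). No stem cell-like or proliferating cell was found among the 138 old cells, where 3 cells would make 2.17% and the 95% interval of each share reaches 2.64%. The younger experiments ran from 0% to 7.74% and from 0.578% to 9.22%, so neither share is shown to be lower. Neuroblast-like cells (12 cells, 8.70%, 4.57 to 14.7) and oligodendrocyte precursor-like cells (21 cells, 15.2%, 9.67 to 22.3) lay within the range of the younger experiments. The niche experiments are called younger on the assumption that their mice were not older than 12 months, since the labels give no age for them. With 1 old library shares were not tested, and age cannot be told apart from the sort and sequencing run of that library. Cluster 7 held 49 of the old microglia-like cells, and the younger ones came mainly from clusters 5 and 8 in experiments 1, 3 and 5 and from cluster 7 in experiment 2. The blood and lymphoid-like share is the sum of cluster 11 (10.9% of old cells) and cluster 12 (9.42%), the latter led by haemoglobin genes and Ttr, which are not immune genes. For class shares in the old library: blood and lymphoid, the share was 0% with seed 3 of the random division and with at least 500 transcripts per cell, where no niche cell had this name either. It was 12.7% with at least 2000, 10.9% at a resolution of 0.6 and 9.42% at 1.5 and with clusters from all counts.

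The Nestin-GFP library held mostly glia of the astrocyte and oligodendrocyte lineages. Astrocyte-like cells made up 29.5% (95% interval 24.5 to 34.9), just above the highest of the 5 niche experiments (28.9%), which the interval includes. Mature oligodendrocyte-like cells made up 29.5% (24.5 to 34.9), above all 5 niche experiments (highest 11.5%). Oligodendrocyte precursor-like cells made up 21.9% (17.5 to 26.9) and neuroblast-like cells 13.3% (9.78 to 17.6). Endothelial-like cells made up 4.13% (2.22 to 6.95), just above the highest of the 5 (4.05%). Microglia-like and proliferating cells were not found (0 of 315, where 3 cells would make 0.952% and the interval of each reaches 1.16%), and blood and lymphoid-like cells made up 1.27% (0.347 to 3.22). Of these, the microglia-like share lay below all 5 experiments, the proliferating share could not be told from the lowest (0.578%), and the blood and lymphoid-like share was under the lowest (3.22%) by a margin that its interval reaches. A single stem cell-like cell was found (0.318%, 0.008 to 1.76). Of the astrocyte-like cells 68 were in cluster L2 and of the mature oligodendrocyte-like cells 85 in cluster 9, which held 10 and 4 niche cells. By contrast, 67 of the precursor-like and 34 of the neuroblast-like cells shared clusters 0 and 4 with 77 and 51 cells of experiment 2. The library is single, so no test was made.

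Neural stem cell-like cells were compared with astrocyte-like cells, a close relative that shares most of their markers, in experiments 2 and 3. Sox1, a transcription factor of neural progenitors (chr8:12395295-12400126), stood at 487 ± 177 CPM (SD, n = 2) against 110 ± 22.5 in astrocyte-like cells, with a log2 fold change of 2.11 ± 0.62 (SE, edgeR adjusted p = 0.0183). Sparc, a secreted matrix glycoprotein (chr11:55394500-55423183), was higher by 2.23 ± 0.43 (3231 ± 341 against 695 ± 243 CPM, edgeR adjusted p = 2.9e-05), and Dkk3, a secreted member of the Dickkopf family (chr7:112116017-112159057), by 1.69 ± 0.56 (560 ± 129 against 168 ± 60.4 CPM, edgeR adjusted p = 0.0447). The potassium channel gene Kcnk1 (chr8:125995170-126030685) had no count in stem cell-like cells and 795 ± 296 CPM in astrocyte-like cells, at least 22.1-fold lower, and the angiogenic factor Vegfa (chr17:46016993-46032369) stood at 244 ± 64.5 against 1256 ± 384 CPM, a log2 fold change of -2.34 ± 0.46.

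Of the 15 immediate early and dissociation response genes tested, 4 were higher in stem cell-like cells and 0 lower (9 and 0 when adjusted over the list alone). Fos, which is induced by stimulation and by tissue dissociation (chr12:85473890-85477273), was higher by a log2 fold change of 2.62 ± 0.47 and Egr1 by 1.80 ± 0.45. Cyr61, a matricellular target of the Hippo pathway, was higher by 3.40 ± 0.55, the adhesion receptor Gpr98 by 2.97 ± 0.74 and the carboxypeptidase Cpd by 2.81 ± 0.90. Among Wnt pathway genes 1 of 5 was higher (3 adjusted over the list alone), among stem and glial transcription factors 1 of 13 (1 over the list alone) and among ribosomal proteins 1 of 66, Rps21 (0 over the list alone). Of 30 astrocyte function genes, 6 were lower and 1 higher (11 and 1 over the list alone), among them the glutamine transporter Slc38a3 (-2.38 ± 0.47) and the endothelin receptor Ednrb (-1.88 ± 0.47). Glycolysis had 3 of 12 genes lower (4 over the list alone), among them the phosphofructokinase genes Pfkm (-2.25 ± 0.53) and Pfkp, with a ratio of 34.5 in favour of astrocyte-like cells (counting interval 5.83 to 1399). Oxidative phosphorylation had 1 of 38 lower, Cox5b (-1.51 ± 0.45), and lipid metabolism 3 of 15, among them Acsbg1 (-1.43 ± 0.42) and Elovl5 (-1.40 ± 0.43). In the extracellular matrix list 3 of 9 were higher and 2 lower, among the latter Hapln1, a link protein of perineuronal matrix (-2.79 ± 0.62). Early oligodendrocyte lineage genes had 3 of 11 lower, among them Olig1 (-2.46 ± 0.71), and late oligodendrocyte genes 3 of 8, among them Sepp1 (-1.96 ± 0.43) and Car2 (-1.62 ± 0.43). Markers of oligodendrocyte precursors summed to 1218 ± 121 CPM in stem cell-like cells and 1601 ± 486 in astrocyte-like cells over all experiments. With camera at the preset correlation, 4 of 21 lists were higher (immediate early, ribosomal, Wnt, and stem and glial factors) and 5 lower (oxidative phosphorylation, astrocyte functions, glycolysis, and early and late oligodendrocyte genes), and none held with an estimated correlation (adjusted p = 0.629 to 0.670). In simulated counts of this pair, a list with 20 of 40 members raised also missed 0.05 with an estimated correlation (unadjusted camera p = 0.0808). The loss of these calls therefore does not tell whether the lists moved.

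In this comparison 99 of 1617 genes differed (28 higher and 71 lower, 281 at an unadjusted p under 0.05), on 37 stem cell-like and 82 astrocyte-like cells with 133104 and 146559 counts. The test rests on 2 experiments, DESeq2 called 1 gene and a fit without the experiment block called 0. The count was 155 with at least 2000 transcripts per cell, 150 with a minimum of 3 cells, 179 with a second random division of the UMIs, 224 with raw UMIs and 424 when the counts that drew the clusters were tested too.

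Progenitor and neuroblast-like cells were then compared with stem cell-like cells in experiments 2 and 3, the step from stem cell to young neuron. The joined group was mostly neuroblast-like, with 95 and 24 such cells in experiments 2 and 3 against 7 and 2 proliferating progenitor-like cells. The genes below therefore tell little of the progenitors alone. Zbtb18, a transcriptional repressor of developing neurons (chr1:177442351-177450764), stood at 1264 ± 181 CPM (SD, n = 2) against 137 ± 91.7, a log2 fold change of 3.11 ± 0.46 (SE, edgeR adjusted p = 5.4e-10), and Stmn1, a regulator of microtubules (chr4:134468320-134473843), at 4050 ± 1874 against 631 ± 484 CPM (2.72 ± 0.35, edgeR adjusted p = 2.5e-13). Mllt11 (457 ± 103 CPM, chr3:95219135-95232171) and the netrin receptor Dcc (255 ± 64.6 CPM, chr18:71253634-72351069) had no count in stem cell-like cells and were at least 15.3-fold and 6.79-fold higher. In the other direction, Clu, a secreted chaperone (chr14:65968483-65981547), fell from 6564 ± 720 to 118 ± 24.6 CPM (-5.67 ± 0.38, edgeR adjusted p = 4.9e-45), Apoe, a lipid carrier (chr7:19696109-19699188), from 18350 ± 79.1 to 673 ± 195 CPM, and the ectonucleotidase gene Entpd2 (chr2:25395874-25401321) from 1103 ± 386 CPM to no count, at least 128-fold.

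Neuronal differentiation factors had 18 of 23 genes higher and 1 lower (18 and 2 adjusted over the list alone), with the RNA-binding protein gene Elavl2 at a ratio of 32.9 (counting interval 9.01 to 273) and Marcksl1 at 2.17 ± 0.35. Of 73 genes in the ribosomal protein list, 58 were higher and 0 lower (59 and 0 over the list alone), such as Rpl5 (1.89 ± 0.36) and Rps3 (1.67 ± 0.38), and DESeq2 called 34. Cell cycle genes had 8 of 15 higher (9 over the list alone), among them Tubb5 (2.47 ± 0.34). All 24 astrocyte function genes tested were lower, also over the list alone, among them Mfge8 (-5.00 ± 0.38). The extracellular matrix list had 6 of 7 lower, among them Sparcl1 (-4.51 ± 0.35) and the tenascin gene Tnc, with a ratio of 92.3 in favour of stem cell-like cells (24.2 to 784). Lipid metabolism had 8 of 13 lower (9 over the list alone). Among growth factors and receptors 5 of 9 were lower and 1 higher (5 and 2 over the list alone), with the neurotrophin receptor Ntrk2 (chr13:58806569-59133970) at 136 ± 20.4 against 2667 ± 199 CPM (-4.35 ± 0.38) and the receptor phosphatase Ptprz1 at -2.94 ± 0.33. In the Hedgehog pathway 3 of 4 were lower, among them Gli3 (-3.60 ± 0.81) and Gas1 (-2.72 ± 0.52). In the Notch pathway 2 of 4 were lower, Notch2 (chr3:98013527-98150361, -4.45 ± 0.59) and the Notch target Hes5 (-3.59 ± 0.63), and among stem and glial transcription factors 5 of 16 were lower and 3 higher, with Sox9 at -2.90 ± 0.34, and neither of these lists was called as a whole. The Wnt pathway had 4 of 6 lower and 1 higher, the catenin gene Ctnnb1 (1.51 ± 0.37), and was not called either. The lists of homeostatic (4 of 6 lower) and disease-associated microglia (8 of 10 lower) and of late oligodendrocytes (3 of 4 lower) moved with Cst3 (-3.43 ± 0.34), Cd81 (-2.47 ± 0.32), Apoe and Car2, which astrocytes also express. Of 22 lists 11 were called with camera, 3 higher (neuronal factors, ribosomal, cell cycle) and 8 lower, and none held with an estimated correlation (adjusted p = 0.550 to 0.617). A simulated list with 20 of 40 members raised was missed in this way too (unadjusted camera p = 0.104).

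In all 744 of 2331 genes differed (331 higher and 413 lower), on 128 and 37 cells with 522512 and 133104 counts from 2 experiments. DESeq2 called 474, of which 33.8% were higher against 44.5% with edgeR, and 241 differed without the experiment block. The count was 1214 when the counts that drew the clusters were tested too.

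**Figure D2:**
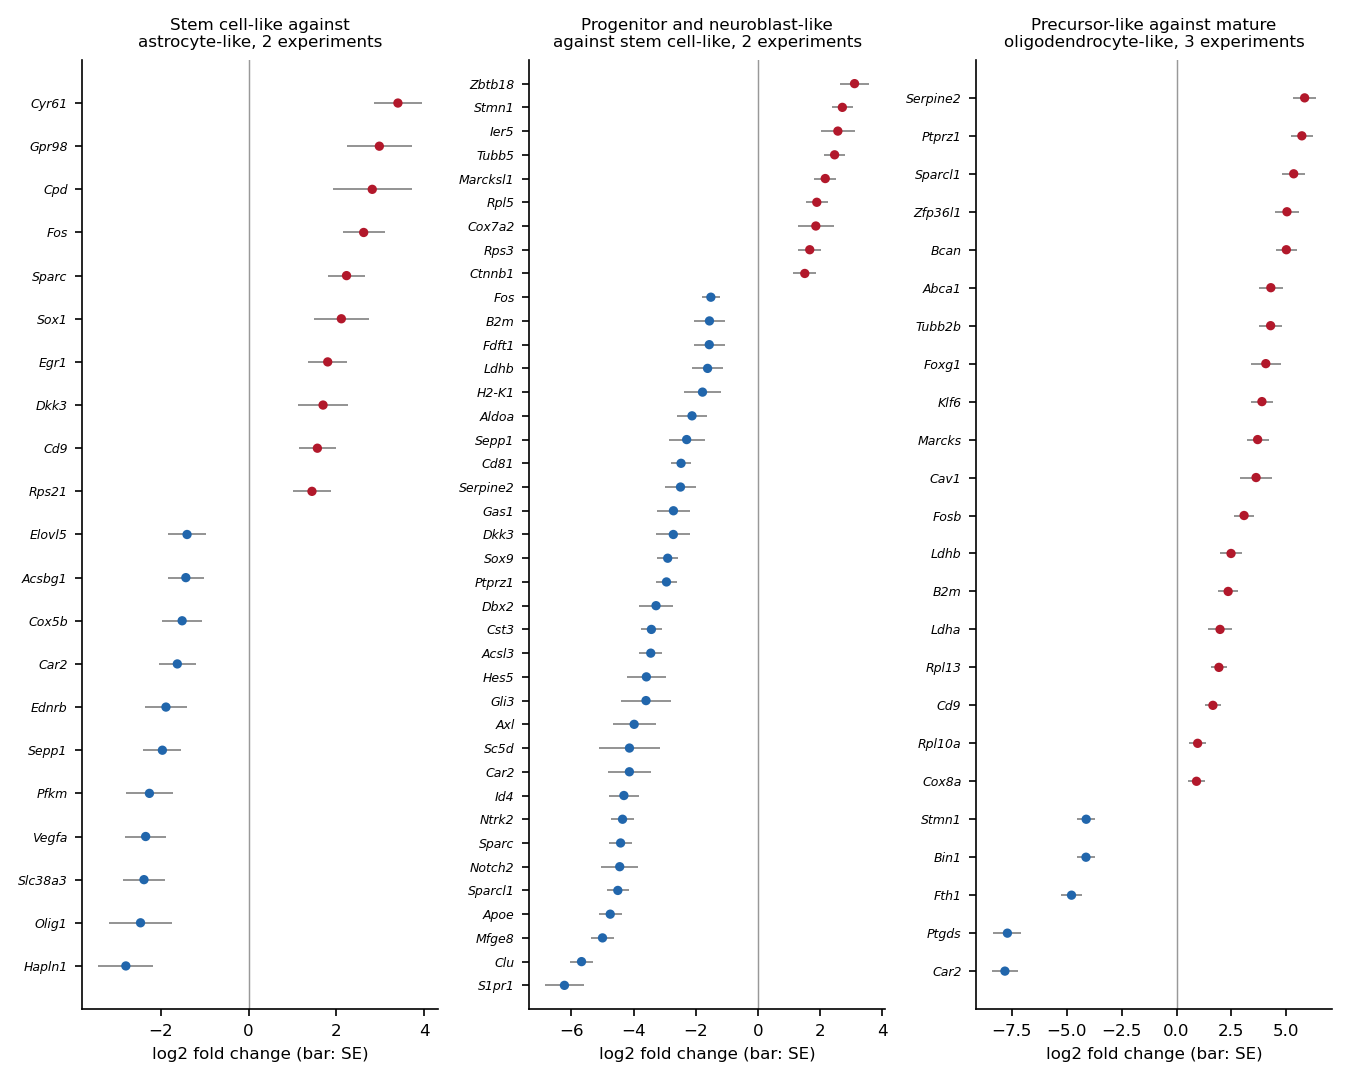
Log2 fold change (x axis) with SE bars of the named genes with more than 3 counts in the lower class, for stem cell-like against astrocyte-like cells (2 experiments), progenitor and neuroblast-like against stem cell-like cells (2 experiments) and oligodendrocyte precursor-like against mature oligodendrocyte-like cells (3 experiments). Folds run from -7.82 for Car2 to 5.84 for Serpine2, both in the oligodendrocyte pair.

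Within the oligodendrocyte lineage, precursor-like cells were compared with mature oligodendrocyte-like cells in experiments 1, 3 and 5. Ccnd1, a cyclin of the G1 phase (1177 ± 237 CPM, SD, n = 3, chr7:144929931-144939925), and the transcription factor gene Sox6 (1055 ± 180 CPM, chr7:115470872-116038796) had no count in mature cells and were at least 41.5-fold and 31.6-fold higher. Ptprz1 (chr6:22875502-23052916) stood at 5821 ± 678 against 133 ± 98.2 CPM, a log2 fold change of 5.71 ± 0.50 (SE, edgeR adjusted p = 7.8e-13). In the other direction, Ptgds, a prostaglandin synthase (chr2:25466709-25470046), stood at 21921 ± 5206 CPM against 91.5 ± 42.2 in precursors (-7.71 ± 0.64, edgeR adjusted p = 2.2e-13), the carbonic anhydrase gene Car2 at 8178 ± 1811 against 19.4 ± 33.6 CPM (-7.82 ± 0.58), and Ndrg1 (2185 ± 778 CPM, chr15:66929318-66969640) had no count in precursors, at least 193-fold lower.

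Of 21 early oligodendrocyte lineage genes, 17 were higher in precursors and 2 lower, with the protease inhibitor Serpine2 at 5.84 ± 0.51 and Ednrb at a ratio of 247 (counting interval 44.1 to 9773). The transcription factor gene Nkx6-2, of the same list, was at least 33.5-fold lower. Of 23 late oligodendrocyte genes, 21 were lower and 0 higher, among them Gpr37 with a ratio of 199 in favour of mature cells (67.5 to 972), the iron storage gene Fth1 (-4.79 ± 0.49), and Hapln2, at least 64-fold lower. Of 17 astrocyte function genes, 12 were higher and 3 lower, with Sparcl1 at 5.34 ± 0.51. Counts for these lists were the same adjusted over the list alone. The 3 lists were the only ones of 17 called with camera, and none held with an estimated correlation (adjusted p = 0.901). Lists that were not called as a whole still held genes that differed. The extracellular matrix list had 5 of 8 higher and 2 lower, with the proteoglycan gene Bcan at 5.00 ± 0.47, and neuronal differentiation factors had 7 of 11 higher and 2 lower. Growth factors and receptors had 5 of 6 higher, and Fgfr2 was the exception with a ratio of 92.4 in favour of mature cells (30.9 to 454). Among lipid genes 3 of 13 were higher, such as Abca1 (4.30 ± 0.54), and 4 lower. Cell cycle genes had 4 of 8 higher and 2 lower, with Stmn1 at -4.12 ± 0.41. The homeostatic microglia list divided between Marcks, higher by 3.70 ± 0.50, and Bin1, at -4.13 ± 0.41.

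For genes differing between oligodendrocyte precursor-like and mature oligodendrocyte-like cells, 743 of 1428 were called (441 higher and 302 lower), on 183 and 66 cells with 415383 and 190344 counts, and DESeq2 called 529. The count was 361 without experiment 1, which held 138 of the precursor-like cells, 440 without the block, 1388 with counts summed per plate and 1404 when the counts that drew the clusters were tested too. Markers of a second class were seen in most precursor-like cells (332 of 365 over all libraries at 1 transcript per marker, 156 at 3 transcripts), and these cells were in the comparison.

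Each of 7 classes was set against the mean of the other 6 to see which of them carry the ligands, receptors and programmes of the fixed lists. Stem cell-like, endothelial-like, fibroblast-like and mature neuron-like cells were in too few experiments and were not part of this comparison. A gene called higher here is higher than the mean of the other 6 classes. It may be as high or higher in some of these 6, and in the classes left out. Astrocyte-like cells expressed the NMDA receptor subunit gene Grin2c at 964 ± 185 CPM (SD, n = 5 experiments) against 5.55 in the mean of the other classes, the folate enzyme Aldh1l1 at 373 ± 150 against 1.66, Atp13a4 at 519 ± 232 against 6.81 and the steroid enzyme Hsd11b1 at 1272 ± 451 against 34.2. All 31 astrocyte function genes were higher, such as Clu (13551 ± 5464 against 277 CPM) and Mlc1 (1896 ± 353 against 29.9). Metabolic genes were higher as groups, with 15 of 21 lipid genes (Acsbg1, 1180 ± 255.9 against 12.3 CPM), 8 of 8 cholesterol synthesis genes (Idi1, 543 ± 134 against 72.9, and Sqle, 439 ± 134 against 57.1) and 12 of 14 glycolysis genes (Pfkm, 593 ± 100 against 60.6). So were 13 of 16 growth factors and receptors (Ntrk2, 2091 ± 427 against 241, and Fgfr1, 983 ± 286 against 105) and 8 of 9 blood-brain barrier and transport genes (Bsg, 851 ± 246 against 302). These 6 lists held with an estimated correlation (camera adjusted p = 0.00434, 0.00195, 0.0103, 0.0161, 0.0348 and 0.0377). Adjusted over the list alone the counts were the same but for glycolysis, with 13. Stem and glial transcription factors (13 of 18, such as Sox9 at 1627 ± 155 against 191 CPM) and the extracellular matrix list (7 of 10, such as Hapln1 at 535 ± 66.9 against 11.3) were called at the preset correlation only (adjusted p = 0.0823 and 0.0664 with an estimated correlation). Ribosomal proteins had 71 of 77 genes lower and 0 higher (adjusted p = 0.12 with an estimated correlation). Id4 (989 ± 272 against 13.4 CPM) and the Notch target Hes5 (342 ± 169 against 42.9) were higher in lists not called as a whole, and Gfap, an astrocyte filament protein, stood at 1187 ± 1121 against 36.5.

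Microglia-like cells expressed the fructose transporter Slc2a5 at 871 ± 393 CPM against 2.37, the purinergic-type receptor Gpr34 at 3648 ± 1472 against 24.1, Fgd2 at 1343 ± 479 against 14.9 and Anxa3 at 1007 ± 299 against 5.04. All 22 homeostatic microglia genes were higher, such as Selplg (7130 ± 2768 against 190 CPM) and Olfml3 (3893 ± 1223 against 41.9). Immediate early genes had 26 of 28 higher, such as Atf3 (4452 ± 2220 against 54.1) and Zfp36 (7736 ± 2652 against 236), and disease-associated microglia genes 14 of 18, such as Cd68 (952 ± 243 against 20.9) and Ctsd (7336 ± 2127 against 356). Antigen presentation (6 of 6, B2m at 4689 ± 1235 against 1071 CPM) and interferon response genes (8 of 9, Irf8 at 919 ± 230 against 74) were higher as well. Cholesterol synthesis had 7 of 8 lower (8 over the list alone) and oxidative phosphorylation 16 of 44 lower (15 over the list alone). Of the 12 lists called here none held with an estimated correlation, the lowest being MHC (adjusted p = 0.0574), homeostatic microglia (adjusted p = 0.0581) and cholesterol synthesis (adjusted p = 0.0664). The ribosomal list had 28 of 77 higher, among them the S6 kinase gene Rps6ka1, but 11 higher and 3 lower with RLE scaling. Among ligands and receptors, Sparc (10480 ± 2432 against 264 CPM), the growth factor Pdgfb (838 ± 403 against 9.98), the receptors Tgfbr1 (2649 ± 935 against 80.1) and Tgfbr2 (757 ± 354 against 36.5), Gas6 (385 ± 207 against 78.8) and Mertk (282 ± 161 against 31.8) were higher. The BMP and TGF-beta list was called in no class.

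Oligodendrocyte precursor-like cells expressed Elfn1 at 211 ± 87.9 CPM against 0.895, the somatostatin receptor Sstr1 at 246 ± 57.2 against 4.75, Susd5 at 322 ± 46 against 10 and Tmem255b at 315 ± 123 against 5.2. Of 25 early oligodendrocyte lineage genes 22 were higher, also over the list alone and with an estimated correlation (camera adjusted p = 0.0103), such as Cntn1 (1342 ± 503 against 47.4 CPM) and Olig1 (4417 ± 1075 against 553). The ligand Bmp4 stood at 304 ± 345 against 4.37 CPM, the Notch ligand Dner at 595 ± 267 against 63.7, Ptprz1 at 3182 ± 1162 against 566 and the lipid transporter Mfsd2a at 493 ± 124 against 32.2. Extracellular matrix genes had 7 of 10 higher, such as Spon1 (863 ± 145 against 36.1), and 61 of 77 ribosomal proteins were lower (67 over the list alone), calls lost with an estimated correlation (adjusted p = 0.0857 and 0.12). The medians of oxidative phosphorylation and immediate early genes changed sign with the scaling here. Mature oligodendrocyte-like cells (n = 3 experiments) expressed Ndrg1 at 1951 ± 900 CPM against 9.37, Ptgds at 19140 ± 6432 against 81.4 and Apod at 2111 ± 829 against 19.1. All 23 late oligodendrocyte genes were higher (camera adjusted p = 0.00434 with an estimated correlation), such as Tspan2 (4525 ± 679 against 39.5 CPM). Cholesterol synthesis had 5 of 8 higher (7 over the list alone) and Notch pathway 4 of 8 lower, calls lost with an estimated correlation (adjusted p = 0.0952 and 0.217). The fatty acid enzymes Fa2h (1718 ± 731 against 31.1) and Elovl7 (719 ± 149 against 24.1) and the receptor Fgfr2 (847 ± 409 against 50.6) were higher too.

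Neuroblast and immature neuron-like cells expressed Elavl2 at 565 ± 280 CPM against 49.5, the transcription factor Neurod2 at 198 ± 135 against 5.45, the guidance ligand Sema3c at 403 ± 200 against 26.3 and Mfap4 at 319 ± 134 against 45.3. Of 26 neuronal differentiation factors 25 were higher, also over the list alone and with an estimated correlation (camera adjusted p = 0.00434), such as Nfib (4589 ± 1889 against 768 CPM) and Crmp1 (578 ± 191 against 57). Stem and glial factors had 12 of 18 higher and 1 lower, such as Lhx2 (1283 ± 197 against 399) and Zbtb20 (1320 ± 438 against 374), and the Wnt pathway 4 of 6, such as Fzd3 (296 ± 205 against 92.9) and Ctnnb1 (1056 ± 228 against 500), while glycolysis had 6 of 14 lower (8 over the list alone). These calls were lost with an estimated correlation (adjusted p = 0.0672, 0.268 and 0.0915). Proliferating progenitor-like cells (n = 3 experiments, 26 cells) expressed the mitotic genes Pbk (688 ± 108 against 6.18 CPM), Ccnb1 (515 ± 98.6 against 6.07), Ccna2 (848 ± 74.2 against 14.3) and Fam64a (392 ± 94.9 against 3.07). Cell cycle genes had 27 of 30 higher and stem and glial factors 13 of 18 (14 over the list alone), and both held with an estimated correlation (camera adjusted p = 0.000209 and 0.0249). Sox1 stood at 617 ± 270 against 49 CPM, and the factor Insm1, of the neuronal list with 12 of 26 higher (14 over the list alone, adjusted p = 0.0664 with an estimated correlation), at 588 ± 172 against 29.

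Blood and lymphoid-like cells expressed the chemokine receptor Ccr7 at 712 ± 618 CPM against none in the other classes, Gimap6 at 634 ± 396 against 10.6, Gimap3 at 423 ± 288 against 1.97 and Cd52 at 1336 ± 456 against 80. All 6 MHC genes tested were higher, also over the list alone and with an estimated correlation (camera adjusted p = 0.0285), among them H2-K1 (3239 ± 1859 against 571 CPM, higher in 4 of 5 experiments) and Cd74 (2274 ± 3131 against 36.3, higher in 2 of 5). Ribosomal proteins had 72 of 77 higher, such as Rpl12 (3711 ± 2209 against 621), and interferon response genes 8 of 9, such as Psmb8 (441 ± 331 against 43.8), calls lost with an estimated correlation (adjusted p = 0.0572 and 0.0857). Rpl12, H2-K1 and Cd74 had a fold change below 0, past no threshold, when the cells were clustered at a resolution of 1.5.

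**Figure D3:**
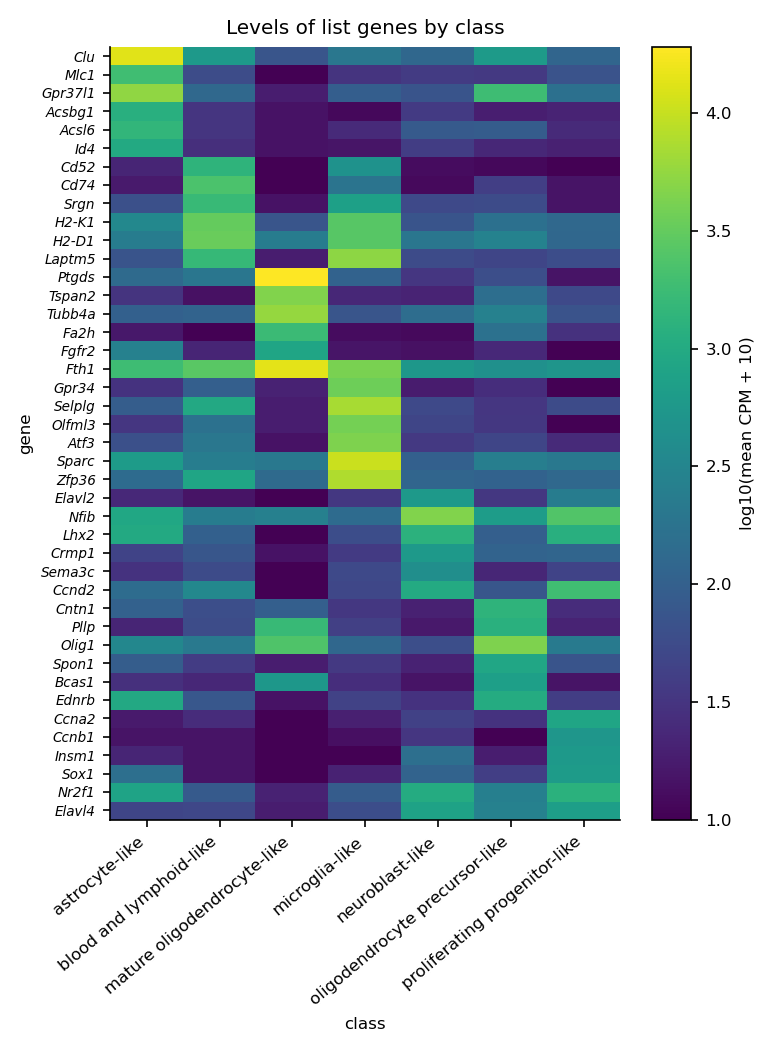
Heat map of 42 list genes (one axis) in 7 classes (other axis), coloured by log10 of mean CPM + 10 over experiments. Clu reaches 13551 CPM in astrocyte-like cells, Sparc 10480 in microglia-like cells and Ptgds 19140 in mature oligodendrocyte-like cells.

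The numbers of genes that differed, of 4165 tested per class with edgeR, were 1729 in microglia-like cells (1172 higher), 1415 in astrocyte-like cells (957 higher), 1121 in oligodendrocyte precursor-like cells (812 higher), 1113 in neuroblast-like cells (613 higher), 1090 in mature oligodendrocyte-like cells (658 higher), 956 in blood and lymphoid-like cells (683 higher) and 656 in proliferating progenitor-like cells (323 higher), 8080 in all for genes of each class against the mean of the other classes. The share that was higher moved with RLE, another scaling in edgeR, and with DESeq2, which changes scaling and test together. It went from 67.6% to 81.7% with RLE and 79.5% with DESeq2 in astrocyte-like cells, from 72.4% to 85.1% with RLE in precursor-like cells, and from 60.4% to 65.5% with RLE and 73.8% with DESeq2 in mature oligodendrocyte-like cells. In microglia-like cells it went from 67.8% to 51.5% with RLE and 47% with DESeq2, in blood and lymphoid-like cells from 71.4% to 47.7% and 46.7%, and in neuroblast-like cells from 55.1% to 46.3% and 40%. The median of all genes shifted with RLE by 0.32 log2 in astrocyte-like, 0.28 in precursor-like and 0.12 in mature oligodendrocyte-like cells, and by -0.32 in microglia-like, -0.32 in blood and lymphoid-like and -0.12 in neuroblast-like cells. Leaving out cells with 3 or more markers of a second class brought the total to 1704, testing genes without the filter on low counts to 12911 and testing all counts to 13855. Across the 161 tests of lists, 72 were called at the preset correlation and 12 with an estimated one.

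Old niche cells were compared with the younger experiments in 4 classes, to see which genes differ with age. The old library is single, so every call here assumes that it varies like the younger experiments. In blood and lymphoid-like cells the haemoglobin gene Beta-s stood at 59557 CPM in the old library against 9.43 ± 21.1 (SD, n = 5 experiments), a log2 fold change of 11.57 ± 1.23 (SE, edgeR adjusted p = 0.000153). It was the 1 gene of 1782 called. Several younger libraries hold haemoglobin under other symbols. As CPM of the total counts, without TMM scaling, Beta-s stood at 32201 in the old library. On that scale haemoglobin summed over all its genes made up 0, 28.8, 445283, 0 and 0 CPM of this class in experiments 1 to 5 and 32314 CPM in the old library. No gene was called in microglia-like (0 of 3356), neuroblast-like (0 of 7137) or precursor-like cells (0 of 3925) with edgeR or DESeq2. The part of tested genes with an unadjusted p under 0.05, 5% by chance, was 2.53% in blood and lymphoid-like, 3.75% in microglia-like, 5.60% in neuroblast-like and 5.61% in precursor-like cells. At the preset correlation, and with no call at an estimated correlation (adjusted p = 0.884), immediate early genes were higher in old blood and lymphoid-like cells as a list (camera adjusted p = 6.13e-07, 0 of 28 genes called, 2 over the list alone, summed level 26496 CPM against 6016 to 18264 in younger experiments). In old microglia-like cells the list was called higher too (adjusted p = 0.00178, 0.814 with an estimated correlation, 0 of 30 called, 2 over the list alone), but its summed level, 71240 CPM, lay below experiments 1 and 5 (72550 and 75975). Astrocyte function genes were lower in old microglia-like cells (adjusted p = 0.00674, 0.814 with an estimated correlation, 0 of 9 called). With a single old library of 28, 54, 12 and 21 cells in blood and lymphoid-like, microglia-like, neuroblast-like and precursor-like cells, a rise of 2 log2 in simulated counts was recovered in 6.52%, 30.6%, 44.7% and 66% of genes and a fall of 2 in at most 12.8%. Without experiment 2, whose files list haemoglobin under the same symbol as the old library, 12 genes were called in microglia-like, 69 in neuroblast-like and 17 in precursor-like cells.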

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

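Of the tests below, only that of depth was chosen before its result was seen. The tests of the shared sequencing run, of age, of haemoglobin symbols and of other splits of the samples were chosen afterwards.

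Stem cell-like cells were sequenced more deeply than astrocyte-like cells, with a median of 6246 against 2088 transcripts per cell in experiment 2 and 6647 against 3265 in experiment 3. A candidate explanation of the 99 genes that differed between them is this difference of depth. With cells of at least 3000 transcripts alone, all 99 kept their direction and their median log2 fold change was 1.01 times that over all cells (bootstrap interval 0.967 to 1.07), 1.94 against 1.91. By the prediction made beforehand this counts against depth, but the test cannot exclude it. The deep cells still differed, with a median of 7691 against 5225 transcripts in experiment 2 (20 and 13 cells) and 7929 against 6192 in experiment 3 (11 and 19 cells). They are also part of the cells in which the 99 genes were called, and the classes were not drawn anew. Depth and other explanations, such as cells of a mixed identity, stay open.

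In old precursor-like cells, 60 genes of at least 100 CPM lay at least 2 times above each of 4 younger experiments (20 CPM added), with a median log2 level of 1.80 over the younger mean, such as Kcnq1ot1 (16132 CPM against 3135), and the same rule gave 4, 6, 152 and 122 genes for experiments 1, 2, 3 and 5 in the place of the old library. The sequencing run that the old and Nestin-GFP libraries share may account for part of this, since the same genes lay above the younger mean by a median of 0.605 in Nestin-GFP precursor-like cells (bootstrap interval 0.438 to 0.930), against 0.0965 to 0.665 for younger experiments held out in turn. Under the first reading of this test, made without the bootstrap interval, 0.605 was within the range held out and counted against the shared run, and the reading was changed after the value had been seen because the interval reaches past that range. Age of the mice, with a median of 1.8 in the old library, is the biological explanation that the design names, and it was not tested because the labels give no age for the Nestin-GFP mice. Run and age cannot be told apart for these genes, picked for being high in the old library, and the makeup of the class stays open too, as 19 of 21 old cells lay in cluster 0 with 77 cells of experiment 2 and 67 Nestin-GFP cells, where experiments 1, 3 and 5 had 0 cells, against 116, 11 and 17 in cluster 1.

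Beta-s was called higher in old blood and lymphoid-like cells, by a log2 fold change of 11.57. A candidate explanation is that haemoglobin was counted under other symbols in other libraries. Summed over every haemoglobin gene, the old library stood at 0.0726 times experiment 3 (32314 against 445283 CPM), as this explanation needs, but at 1120 times experiment 2 (28.8 CPM), which counts it under the same symbol, and experiments 1, 4 and 5 had 0, so it does not account for the difference from experiment 2. Cluster 12 accounts for nearly all of these counts in experiment 3 and the old library. Haemoglobin made up 63.1% of its counts in experiment 3 (10 cells), 9.85% in the old library (13 cells) and 0.00354% in experiment 2 (30 cells). In experiment 2 clusters 11 and 12 each held 1 haemoglobin count, whereas the neuroblast-like cluster 6 held 222. The haemoglobin of experiment 2 thus lay mostly outside this class, and the contrast with it holds for the class alone. No biological explanation was tested.

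For the class comparison, 1 of 40 draws of the class names within experiments, the real one, gave as many genes (8080, the highest other draw 567), but the classes were drawn from the expression of the same cells, so this does not tell whether chance can be excluded. For the oligodendrocyte pair, 1 of 10 splits, the real one, gave as many genes (743, the highest other split 0), and 10 splits are too few for a share under 0.05.

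The Nestin-GFP library holds 408 counts of the GFP construct, in 154 of 328 wells of at least 500 transcripts with mitochondrial ones counted, and none of 1602 niche and 167 old wells held any. Mitochondrial transcripts made up 9.71% of the Nestin-GFP library and 6.8% of the old library, and the other files list none.

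In 2 of 11 class shares a single experiment stood far from the rest by Dixon's criterion. For fibroblast-like cells the gap took 0.858 of the whole range (9.22% in experiment 4) and for proliferating progenitor-like cells 0.854 (9.22% in experiment 4). The same was found in 16 of 232 groups of gene levels (6.90%), where chance gives about 1 in 20. In astrocyte-like cells these were Atp13a4 (0.724 of the range), Bcan (0.818), Cd44 (0.788), Dbx2 (0.728) and Serpina3n (0.804). In blood and lymphoid-like cells they were Bcl11a (0.818), Cdkn1a (0.909), H2-D1 (0.785), Nr4a1 (0.842), Srgn (0.728) and Vim (0.757). In microglia-like cells they were Klf2 (0.725) and Rps29 (0.839), and in oligodendrocyte precursor-like cells Bmp4 (0.817), Dner (0.955) and Olig1 (0.716).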

How the results depend on the processing

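The alternatives of mitochondrial genes counted toward the minimum, random divisions of the UMIs with seeds 2 and 3, the second-class filter at 3 or more transcripts each, and at least 3 cells per class and experiment were chosen after seeing the data. The stem cell-like cells of the pairs held 133104 counts and the proliferating class 123472 counts, and the old comparison rests on a single library. Whether depth limits these results was not tested. The alternatives that gave values numbered 17 for each pair with stem cell-like cells, 20 for the oligodendrocyte pair and 23 for classes, and a case is counted only where the gene was tested. Of the named genes, the 33 of the stem cell and astrocyte pair kept direction and threshold in 434 cases and only the direction in 112, the 55 of the neurogenic pair in 854 and 39, the 45 of the oligodendrocyte pair in 856 and 29, and none of these cases turned. The 291 gene and class pairs of the class comparison kept both in 6045 cases and only the direction in 389, and the direction turned in 37. Causes were not tested unless the setting itself names one.

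The count of genes differing between neural stem cell-like and astrocyte-like cells, 99, was 155 with at least 2000 transcripts per cell, 150 with at least 3 cells per class and experiment, 179 with seed 2, 224 with raw UMIs, 424 with clusters and tests from all counts and 1 with the DESeq2 Wald test. That of genes differing between neurogenic progenitor or neuroblast-like and neural stem cell-like cells, 744, was 1214 with clusters and tests from all counts and 474 with DESeq2. That of genes differing between oligodendrocyte precursor-like and mature oligodendrocyte-like cells, 743, was 1404 with clusters and tests from all counts, 1388 with counts summed per plate, and 361 (without experiment 1) to 919 (without experiment 5) with an experiment left out. That of genes of each class against the mean of the other classes, 8080, was 13855 with clusters and tests from all counts, 12911 with no filter beyond 1 count and 1704 without cells holding markers of a second class. The setting of all counts also draws the clusters anew and tests more counts per gene, and the cause of its higher numbers was not tested. Without the replicate block, that is without pairing classes by experiment, the counts were 0, 241 and 440 for the 3 pairs.

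With an estimated correlation, lists called fell to 12 in the class comparison and to 0 in each of the 3 pairs and the old comparison. A simulated list with 20 of 40 members raised then had an unadjusted camera p of 0.0808, 0.104 and 0.0187 in the 3 pairs. It was 0.00272 to 0.105 in the old comparison and 1.92e-08 in the class comparison. In the pairs with stem cell-like cells the loss of calls is therefore no evidence against a list.

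Of genes differing between old and younger niche by class: blood and lymphoid, 1 in all, 0 were called at resolution 0.6, at resolution 1.5 and with clusters and tests from all counts, 3 with no filter and 32 with at least 2000 transcripts per cell. For genes differing between old and younger niche by class: microglia, 1 was called with seed 2, seed 3 and at least 2000 transcripts, and 48 with no filter. For genes differing between old and younger niche by class: neuroblast and immature neuron, 36 were called with no filter. For genes differing between old and younger niche by class: oligodendrocyte precursor, 21 were called with no filter, 1 with raw UMIs and 2 with seed 3. With an experiment left out the ranges were 0 to 1, 0 to 12, 0 to 69 and 0 to 17, the highest of the last 3 without experiment 2.

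The blood and lymphoid class depended most on the clustering. For class shares in the niche: blood and lymphoid, 7.53% became 0% with seed 3 and at least 500 transcripts, 3.26% at resolution 1.5 and 3.40% with all counts. For class shares in the old library: blood and lymphoid, 20.3% became 0% with seed 3 and at least 500 transcripts, 12.7% with at least 2000, 10.9% at resolution 0.6, 9.42% at resolution 1.5 and 9.42% with all counts. For class shares among Nestin-GFP cells: blood and lymphoid, 1.27% became 0% with seed 3, at least 500 and at least 2000 transcripts, resolution 0.6 and the second-class filter, and 0.318% with all counts. Fibroblast-like cells made up 6.78% of the old library with at least 2000 transcripts per cell, and at resolution 0.6 10.9% of the old and 1.27% of the Nestin-GFP library. Among Nestin-GFP cells, endothelial-like cells made up 2.10% with at least 2000 transcripts per cell, proliferating cells 1.27% with clusters and tests from all counts, and stem cell-like cells 0% with seed 2, with mitochondrial transcripts counted toward the minimum and with the second-class filter. For class shares in the niche: mature neuron, the mean was 2.24% over libraries and 1.56% over plates.

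Without cells holding markers of a second class, few cells were left. In the Nestin-GFP library astrocyte-like cells then made up 22.2%, mature oligodendrocyte-like cells 66.7% and endothelial-like and precursor-like cells 0%. For class shares in the niche: oligodendrocyte precursor, the share was 4.08%. In the old library microglia-like cells made up 68% and endothelial-like, fibroblast-like, mature oligodendrocyte-like, neuroblast-like and precursor-like cells 0%. With the filter at 3 or more transcripts each, precursor-like cells made up 10.4% of the Nestin-GFP and 5.79% of the old library.

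The directions that turned were nearly all in the blood and lymphoid class, none past the threshold. With clusters and tests from all counts the log2 fold change was -0.022 for Id2, -1.45 for Nr4a1, -0.91 for Rpl12, -0.72 for Smc4, -1.45 for Ugcg and -6.80 for Vim in genes of each class against the mean of the other classes: blood and lymphoid, and -0.10 for Bsg in microglia-like cells. With raw UMIs it was -0.083 for Btg1, -0.9997 for Gpi1 in genes of each class against the mean of the other classes: blood and lymphoid, -0.073 for H2-D1 in genes of each class against the mean of the other classes: blood and lymphoid, -0.96 for Id2, -1.11 for Ndufa6, -5.03 for Nr4a1, -1.15 for Rpl12, -0.23 for Rpl39, -0.23 for Rps16 and -5.85 for Vim. At resolution 1.5 it was -0.064 for Btg1, -1.91 for Cd74 in genes of each class against the mean of the other classes: blood and lymphoid, -4.54 for Cdkn1a in genes of each class against the mean of the other classes: blood and lymphoid, -1.14 for Gpi1, -0.21 for H2-D1, -0.49 for H2-K1, -0.79 for Id2, -0.59 for Ndufa6, -4.66 for Notch2 in genes of each class against the mean of the other classes: blood and lymphoid, -5.34 for Nr4a1 in genes of each class against the mean of the other classes: blood and lymphoid, -0.89 for Rpl12, -0.25 for Rps16, -0.0047 for Smc4 in genes of each class against the mean of the other classes: blood and lymphoid and -1.37 for Vim. Without cells holding markers of a second class it was -2.15 for Cdkn1a, -0.55 for Fosb in precursor-like cells and -0.038 for Pfkm in genes of each class against the mean of the other classes: oligodendrocyte precursor. With an experiment left out it ran from -0.14 (without experiment 4) to 3.25 for Cdkn1a, from -0.078 (without experiment 4) to 1.56 for Sepp1 and, from -4.44 (without experiment 1) to 2.91 for Hspa1a in genes of each class against the mean of the other classes: mature oligodendrocyte.

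Not run, for want of cells or experiments, were the second-class filter for the 3 pairs and for old blood and lymphoid-like, neuroblast-like and precursor-like cells, the stricter filter for old precursor-like cells, the old blood and lymphoid comparison at 500 transcripts, with raw UMIs and with seed 3, and the pairs with stem cell-like cells without experiment 2 or 3.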

Other observations

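The test named in the last paragraph was chosen after the values had been seen, and all values here but the edgeR value of Hspa1b are descriptions without a test between groups.

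The GFP construct of the Nestin-GFP library was found more in cells of the oligodendrocyte lineage than in neuroblast-like and astrocyte-like cells. Oligodendrocyte precursor-like cells held 489 CPM of it (Poisson interval 428 to 556, counting error only), in 58 of 69 cells (84.1%), and mature oligodendrocyte-like cells 143 CPM (116 to 174), in 47 of 93 (50.5%). Endothelial-like cells held 126.4 CPM (34.4 to 324), in 3 of 13, neuroblast-like cells 91.3 CPM (59.7 to 134), in 14 of 42 (33.3%), and astrocyte-like cells 90.1 CPM (64.9 to 122), in 30 of 93 (32.3%). The median depth of these classes was 6626, 7299, 1758, 6330 and 4102 transcripts per cell. The endogenous gene Nes, which encodes an intermediate filament of neural progenitors and endothelial cells, followed another order. It stood at 379 CPM (196 to 662) in endothelial-like, 28.1 CPM (12.1 to 55.4) in neuroblast-like, and 14.6 CPM (5.88 to 30.1) in precursor-like cells of that library. Astrocyte-like and mature oligodendrocyte-like cells each held 1 count of it, under the floor of 3 counts, at 2.14 CPM (0.0543 to 12) and 1.45 CPM (0.0367 to 8.07). In stem cell-like cells of the niche, Nes stood at 28 CPM (9.10 to 65.4) in experiment 2 and 67.8 CPM (24.9 to 148) in experiment 3. Per the labels this library holds GFP-positive cells.

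Hspa1b, an inducible chaperone, stood at a log2 fold change of 5.31 in old blood and lymphoid-like cells (edgeR adjusted p = 0.0568 over all genes tested). It is 1 of the 2 immediate early and dissociation response genes called over the list alone, and was chosen after its value was seen. Of 2594 genes with at least 100 CPM in old precursor-like cells, 864 (33.3%) lay above every one of 4 younger experiments, where chance gives 20% and the minimum, set on the old library, raises the share. Of the 60 genes that lay above by at least 2 times, Kcnq1ot1 stood at 16132 CPM in old, 10159 CPM in Nestin-GFP and 3135 CPM in younger cells. Over these genes the Nestin-GFP median lay 0.605 log2 above the younger mean.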
